A study of Homo sapiens with 27 samples.

How the data were processed

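RNA of the HT-29 line was measured on 27 Affymetrix human genome arrays, 18 of an apratoxin A set and 9 of a stress set. The deposited values were linear intensity per probe set, 1 column per array, without replicates pooled. The submitters' processing notes name GCRMA, with its version not given, for the 9 stress arrays. For the other 18 the method is not given in the sources used here. The deposited intensity values of both sets were on a linear scale, 18.9% to 25.6% of them below 0 per array. Array medians differed by up to 2.09 log2 in the apratoxin set and 1.3 log2 in the stress set. GCRMA values are on a log scale and without negatives, so the stress values were treated as background-subtracted intensities without normalization between arrays. Array header files named the chip type and held no measurements, hybridization dates or batches, and were not used.

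Of 22283 probe sets, 68 were control probe sets and left out. The probe table gave 1 gene symbol for 19071 probe sets and several for 1043, which were not named, and did not list 2169. Symbols were updated to those of GRCh38.p14 through the Entrez identifier for 19059 probe sets, without coordinates, since no build is named for the array. Each gene was represented by its probe set with the highest mean over the arrays of a set, and probe sets that disagreed are given beside many of the genes named, but not beside list members.

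Values below 0 were set to 0, 16 was added and log2 taken, so the lowest possible value was 4 and folds of dim genes are understated. Setting negative values to 0 was added when the values were seen, because some lay further below 0 than the pseudocount and then have no logarithm. Because array medians differed by more than 0.25 log2, quantile normalization within each set preceded the log, by the rule fixed for this case. Genes above their array's median over all probe sets on at least 2 arrays of a set were tested, 8002 in the apratoxin set and 7482 in the stress set, of 11963. No batch is given by labels or files, and no identical columns were found.

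Groups came from sample titles. For 2 arrays, vehicle 3 h replicate 2 and 2 nM 12 h replicate 2, the description field named another treatment (2 nM at 3 h and 10 nM at 12 h). Their titles and source names gave the same treatment as each other, and the titles were used. Replicate numbers of the apratoxin set are in deposit order only and those of the stress set come from the titles.

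Each set was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes) with 1 coefficient per group and no covariates. Arrays of a set shared 1 estimate of the spread, with 9 residual degrees of freedom in the apratoxin set and 4 in the stress set. The median SD was 0.2 and 0.13 log2. The UV-200 group, with 1 array, took the spread of the other groups. Tests were two-sided with Benjamini-Hochberg adjustment over genes at a threshold of 0.05. Comparisons were each dose with the vehicle of its time, 10 nM with 2 nM at each time, the 10 nM response at 12 h with that at 3 h (interaction), vehicle at 12 h with 3 h, each stress with untreated arrays, and UV-200 with UV-50. The arrays' own GAPDH and ACTB control probe sets gave 3' to 5' signal ratios, and 9 spike-in probe sets gave array brightness.

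Before the data were examined, 21 gene lists were fixed: FGF receptors and proximal signalling, ERK feedback and output genes, IL-6 family receptors with JAK and STAT, STAT3 target genes, growth factor receptors, the translocon with signal recognition and signal peptidase, ER chaperones and ER-associated degradation, ATF4 and CHOP targets, heat shock response, p53 and DNA damage targets, NRF2 targets, G1/S and DNA replication, G2/M, cholesterol synthesis, immediate early genes, interferon-stimulated genes, NF-kappaB and chemokine genes, cytosolic ribosomal proteins, intestinal epithelial markers, mesenchymal markers, and leukocyte and erythroid markers. Lists share some genes. Each was tested with camera (preset correlation 0.01), with camera and an estimated correlation, and with fry, adjusted over 210 pairs of a list and a comparison with vehicle or untreated arrays. Another 5 lists were chosen after seeing the data. Of the 210 pairs, 46 were called with the preset correlation, 32 upward and 14 downward, and 11 with an estimated one. The 11 were ATF4 and CHOP targets at 6 h and 12 h of both doses, heat shock genes at 3 h and 6 h of both doses and 12 h of 2 nM, ERK output genes at 3 h of 10 nM, and NRF2 targets after hydrogen peroxide. The estimated setting could be stricter even where the estimate lay below the preset. For ATF4 and CHOP targets between the doses at 12 h the estimate was -0.01, yet camera's unadjusted p rose from 1.71e-08 to 0.000117. A call lost with an estimated correlation thus need not reflect correlation between genes.

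Genes were named by a rule fixed at the same time: past the threshold with all treated arrays beyond all control arrays, ranked by size. They were up to 12 in each direction for 10 nM at 12 h and 6 h, 6 for other comparisons with controls, and 3 for 10 nM against 2 nM, the interaction and UV-200 against UV-50. Where none passed they were the 2 in each direction with the largest moderated statistic. FGFR1 to FGFR4, IL6ST, STAT3, JAK1, HSPA5 and DDIT3 were always followed, and up to 4 members of each list with the smallest p. Some were left out for length.

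Correlations between comparisons with shared controls stand beside 50 simulations of unchanged groups against the same arrays. Alternatives were the deposited values without normalization, no filter, all single-symbol probe sets, only the groups compared, leaving out the 2 arrays with conflicting labels, the replicate number as a block (stress set), and each array left out. Added after seeing the data were 1 scaling factor per array, a floor of 16 without pseudocount and a pseudocount of 64. The fit was tested on simulated data. Spreads were those shared by all arrays of a set, so the noise of 1 group alone was not simulated. Changes of 0.5, 1 and 2 log2 added to 10 nM at 12 h (7910 genes) were recovered in 7.9%, 65.7% and 87.5% of genes. There 7 of 7695 unchanged genes were called. When added to UV-50 (7260 genes) the shares were 30.2%, 75.8% and 97%, with 9 of 7047 unchanged genes called. A list shifted by 0.5 was called in both and 0 of the other lists. The simulated noise was independent between genes, so this cannot show how often correlated genes give false list calls. Smaller list shifts were not simulated. Figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.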

Results

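HT-29, a human colorectal adenocarcinoma cell line, was profiled on 27 Affymetrix human genome arrays of 22283 probe sets. In 18 of them the cells had received ethanol vehicle or apratoxin A, a cyclic depsipeptide from cyanobacteria with cytotoxic activity, at 2 nM or 10 nM. Treatment lasted 3 h, 6 h or 12 h, with 2 arrays in each of the 9 groups. The other 9 arrays came from cells that were untreated or had been exposed to heat shock for 1 h, hydrogen peroxide, or ultraviolet light at 50 or 200 J per square metre (UV-50 and UV-200), all at 12 h. Each stress group had 2 arrays except UV-200, which had 1, and UV-200 replicate 1 was not analysed here. Array medians ranged from 13.33 to 56.57 intensity units in the apratoxin set and from 11.99 to 29.45 in the stress set. Of the values on an array, 18.9% to 25.6% were below 0. Arrays of the same group correlated at r = 0.957 to 0.976 in the apratoxin set and at 0.982 to 0.988 in the stress set, across probe sets. The UV-200 array correlated at r = 0.898 with its closest array. The most alike arrays of different groups correlated as closely as replicates, at 0.978 in the apratoxin set and 0.988 in the stress set. Between groups the median r was 0.963 and 0.96, and the lowest 0.938 and 0.867. Changes are given as log2 fold change ± SE on the log2(intensity + 16) scale, and values of a group as mean ± SD on that scale. Nothing in the labels says that replicate arrays came from separate cultures, so p-values measure the spread between these arrays, which may be technical. The number of arrays limits the precision.

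The series title names antagonism of fibroblast growth factor signaling and of STAT3 activation as the property under study. Each dose was set against the vehicle of its own time point. After 12 h of 10 nM apratoxin A, 5 of the 12 highest genes by the naming rule (CHAC1, DDIT4, SLC3A2, ASNS and PSAT1) were members of the list of ATF4 and CHOP targets fixed beforehand. CHAC1, which degrades glutathione, rose 6.59-fold (2.72 ± 0.21, from 5.48 ± 0.18 to 8.2 ± 0.11, n = 2 per group, adjusted p = 6.87e-05). DDIT4, an inhibitor of mTORC1, rose 6.41-fold (2.68 ± 0.18, adjusted p = 2.26e-05). SLC3A2, the heavy chain of several amino acid transporters, rose 5.87-fold (2.55 ± 0.16, adjusted p = 1.24e-05). ASNS, asparagine synthetase, rose 3.46-fold (1.79 ± 0.14), and PSAT1, an enzyme of serine synthesis, rose 3.24-fold (1.7 ± 0.22). WNT10B, a Wnt ligand, rose by 2.39 ± 0.3 from close to the lowest value the scale allows, and DEPTOR, another mTOR inhibitor, rose by 1.63 ± 0.27. The other higher genes by size were CD1A (1.59 ± 0.29), LAT2 (1.55 ± 0.34, with a second probe set at -0.34) and G0S2 (1.54 ± 0.31). GP2 and FUT1 (1.76 ± 0.35 and 1.74 ± 0.33) lay at the floor in vehicle arrays, so that their folds depend on the pseudocount. Of 3 other GP2 probe sets 1 lay at 0.

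The lowest genes at 10 nM and 12 h belonged to no one group. PCSK7, a proprotein convertase of the secretory pathway, fell (-2.49 ± 0.28, from 7.07 ± 0.06 to 4.58 ± 0.82, close to the floor, n = 2, adjusted p = 0.00172). SMPD3, a neutral sphingomyelinase (-2.32 ± 0.36), and ZMAT5 (-2.06 ± 0.32) fell to the floor of the scale on both treated arrays. The kinesin genes KLC2 (-1.89 ± 0.29) and KIF1C (-1.6 ± 0.31) and the phospholipase PLCG1, which receptor tyrosine kinases activate (-1.66 ± 0.37, adjusted p = 0.0462), were also lower. DPH5 (-2.38 ± 0.39), LAIR1 (-1.72 ± 0.38), BRF1 (-1.68 ± 0.33) and KIF1C each had other probe sets at or above 0. In all 150 of 8002 genes passed an adjusted p of 0.05 with limma, 82 higher and 68 lower. That count fell to 37 without vehicle 12 h replicate 1, to 40 without vehicle 12 h replicate 2 and to 40 without 10 nM 12 h replicate 2. On the deposited intensities without normalization, where the median of all genes lay at -0.97, 38 genes passed and all were lower. The count of 150 and the SE assume that these groups vary like the other arrays of the set. The 10 nM 12 h arrays were the least alike replicates of the set (r = 0.957), and PCSK7 had an SD of 0.82 on them. With only the groups compared, which leaves few residual degrees of freedom, no gene passed (limma). CHAC1, DDIT4, SLC3A2, WNT10B, ASNS, PSAT1, PCSK7 and the chaperone HSPA5 passed whichever single array was left out.

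**Figure D1:**
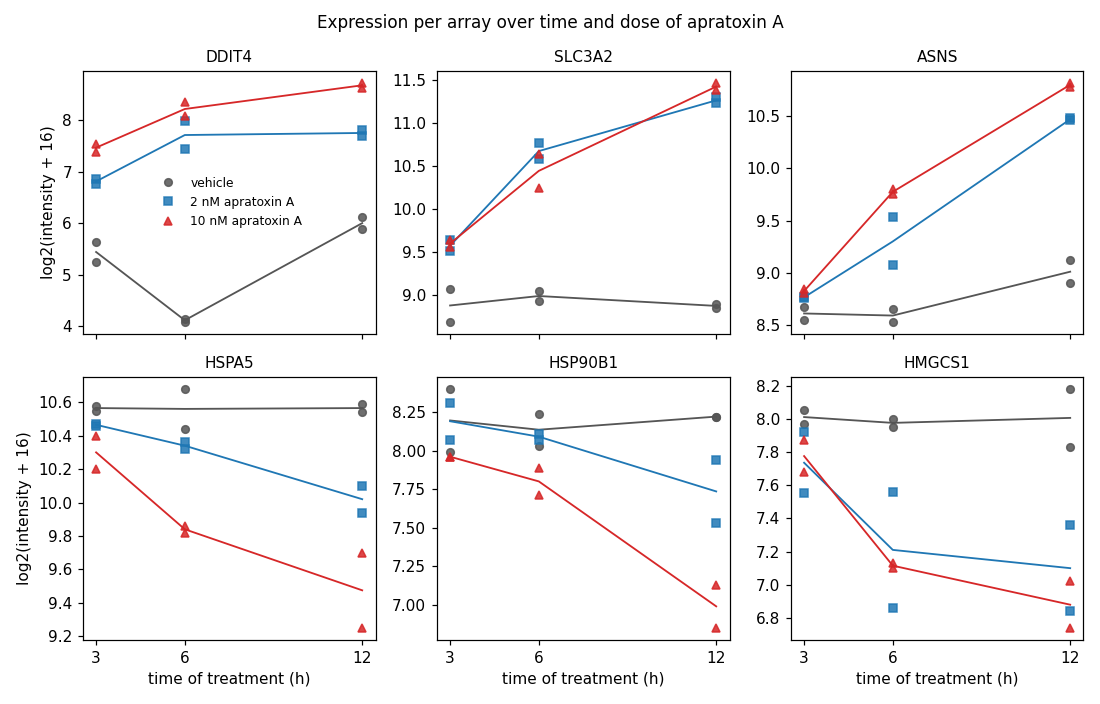
Expression of 6 genes on each array, as log2(intensity + 16), against hours of treatment for vehicle (grey circles), 2 nM (blue squares) and 10 nM apratoxin A (red triangles), with 2 arrays per group and lines through the group means. DDIT4 at 12 h lay at 8.63 and 8.73 on the 10 nM arrays, 7.69 and 7.82 on the 2 nM arrays and 5.89 and 6.12 on the vehicle arrays, while HSPA5 lay at 9.7 and 9.25, 10.1 and 9.94, and 10.54 and 10.59.

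Targets of ATF4 and CHOP, the transcription factors of the integrated stress response, rose as a group at 10 nM and 12 h. Of 32 measured members, 19 rose over all genes tested and 29 when adjusted over the list alone, and none fell. The median change was 0.81 (camera, adjusted p = 5.39e-34, and adjusted p = 1.68e-05 with an estimated correlation). DDIT3, which encodes CHOP, rose 2.03-fold (1.02 ± 0.2, adjusted p = 0.0284). Chaperones of the endoplasmic reticulum (ER) moved apart from these. HSPA5, the main ER chaperone BiP, fell 2.13-fold (-1.09 ± 0.15, from 10.56 ± 0.03 to 9.47 ± 0.32, n = 2). HSP90B1 fell by 1.23 ± 0.18 and PDIA4, a disulfide isomerase, by 0.97 ± 0.13, whereas HERPUD1, a component of ER-associated degradation, rose by 1.18 ± 0.17. Over that list of 24 measured genes 5 fell and 2 rose (10 and 3 adjusted over the list alone), with a median of -0.37 (camera, adjusted p = 0.00283, but adjusted p = 0.0543 with an estimated correlation). Without 10 nM 12 h replicate 1 that median was -0.24 (adjusted p = 0.0306). Cholesterol synthesis genes were lower, with HMGCS1 at -1.13 ± 0.24, SQLE at -0.81 ± 0.17 and IDI1 at -0.83 ± 0.19. Of 18 members 3 were lower over all genes and 6 adjusted over the list alone (median -0.3, camera adjusted p = 0.00243, adjusted p = 0.0514 with an estimated correlation). The GAPDH 3' to 5' signal ratio, a sign of RNA quality, was 1.63 and 1.6 on these 10 nM arrays against 1.36 and 1.36 on their vehicle arrays and 1.28 and 1.2 on the 2 nM arrays. The ACTB ratio went the other way, 1.25 and 1.19 against 1.3 and 1.41 on vehicle and 1.11 and 1.15 on 2 nM arrays. The array 10 nM 12 h replicate 2 was the dimmest array of the set (median 13.33).

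Smaller shifts of 5 more lists passed at 10 nM and 12 h with the preset correlation and none of them with an estimated one. The translocon list, which covers entry into the ER, had a median of 0.13 and 3 of 22 members higher (6 adjusted over the list alone). Among them were TRAM1 (0.56 ± 0.11), SRPRB (0.57 ± 0.12) and SEC62 (0.75 ± 0.17), and the list had a camera adjusted p = 0.00447 and an adjusted p = 0.17 with an estimated correlation. Heat shock genes had a median of 0.14, with HSPH1 (0.7 ± 0.12) and HSPB1 (0.83 ± 0.15) higher among 21 (3 adjusted over the list alone; camera adjusted p = 0.00987, adjusted p = 0.08 with an estimated correlation). NRF2 targets had a median of 0.11 with SLC7A11, the cystine transporter subunit and also an ATF4 target, higher among 23 (1.05 ± 0.17; 2 adjusted over the list alone; camera adjusted p = 0.0275, adjusted p = 0.326 with an estimated correlation). Genes of G1/S and DNA replication had a median of -0.15 and those of G2/M -0.12. No member of 33 or of 41 passed the test over all genes or adjusted over the list alone, such as MCM4 at -0.49 ± 0.15 and CENPE at -0.56 ± 0.16 (limma, with 1248 of 8002 genes below an unadjusted p of 0.05). Their camera adjusted p were 0.0189 and 0.0275, and 0.0928 and 0.232 with an estimated correlation. The NRF2 call was lost without vehicle 12 h replicate 1 (adjusted p = 0.0816), 10 nM 12 h replicate 1 (0.0626) or replicate 2 (0.0833). The G1/S call was lost without vehicle 12 h replicate 2 (0.11) or 10 nM 12 h replicate 1 (0.189), and the G2/M call was lost without vehicle 12 h replicate 1 (0.0545), replicate 2 (0.0612) or 10 nM 12 h replicate 1 (0.194). The translocon, heat shock and NRF2 calls were lost on the deposited intensities (adjusted p = 0.87, 0.883 and 0.865).

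Of genes in the pathways that the series title names, FGFR1 to FGFR4, IL6ST, JAK1 and STAT3 showed no change past the test at 10 nM and 12 h. The receptor genes FGFR1 (-0.03 ± 0.3), FGFR2 (0.44 ± 0.19), FGFR3 (-0.56 ± 0.21) and FGFR4 (-0.02 ± 0.19) had adjusted p of 0.982, 0.276, 0.207 and 0.98. IL6ST, the shared receptor subunit of the IL-6 family, lay at 0.25 ± 0.13 (adjusted p = 0.384), JAK1 at 0.23 ± 0.16 (adjusted p = 0.535) and STAT3 at -0.14 ± 0.16 (adjusted p = 0.721), with another STAT3 probe set at -1.46. Other probe sets lay at -0.73 to 0.4 for FGFR1 (2 of 5 opposite), -0.41 to 0.1 for FGFR2 (7 of 9 opposite), 0.07 for FGFR3, -0.85 for FGFR4 and -0.08 to 0.65 for IL6ST (1 of 4 opposite). In the list of FGF receptors and proximal signalling 1 of 18 members passed, PLCG1, which was lower (1 also adjusted over the list alone). The list had a median of 0.07 but a mean of -0.07 (camera, downward, adjusted p = 0.929). In the list of IL-6 family receptors, JAK and STAT 0 of 13 passed over all genes or over the list alone, among them STAT5B at -0.64 ± 0.19 (median -0.14, adjusted p = 0.417; limma, 1248 genes below an unadjusted p of 0.05). Of 20 STAT3 target genes 0 passed over all genes, with the same tool and 1248 genes, and 2 were higher adjusted over the list alone (median 0.11, adjusted p = 0.285). These were led by CEBPB at 0.59 ± 0.16 and VEGFA at 0.78 ± 0.23. Output and feedback genes of ERK had a median of 0.15 (adjusted p = 0.68, 0 of 19 past the test over all genes or over the list alone). These arrays measure transcript levels, not receptor activity or STAT3 phosphorylation.

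For the remaining lists at 10 nM and 12 h camera gave no call. Growth factor receptors had a median of 0.01, a mean of -0.03 and an upward test (adjusted p = 0.858), with ACVR1B higher among 17 (0.76 ± 0.14; 2 adjusted over the list alone). Among p53 and DNA damage targets GDF15 (0.78 ± 0.15) and PMAIP1 (1.04 ± 0.23) were higher of 21 measured (3 adjusted over the list alone, median 0.1, adjusted p = 0.446). Among immediate early genes ATF3 was higher (0.88 ± 0.18) and CCN1 lower (-1.26 ± 0.24) of 24 (4 and 2 adjusted over the list alone, median 0.06, adjusted p = 0.417). Interferon-stimulated genes (median 0.09, adjusted p = 0.155, 25 measured), NF-kappaB and chemokine genes (0.09, 0.97, 19 measured) and cytosolic ribosomal proteins (0.03, 0.677, 51 measured) had 0 members past the test over all genes or over the list alone. The same held for intestinal epithelial markers (-0.02, 0.966, 21 measured, mean 0.01). Markers of mesenchymal cells (-0.28, 0.542, 11 measured) and of leukocytes and erythroid cells (-0.15, 0.717, 11 measured), which stand for other cell types, also had 0 (limma, 1248 genes below an unadjusted p of 0.05).

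At 6 h, 10 nM apratoxin A raised DDIT4 by 4.1 ± 0.18 from close to the floor (n = 2 per group, adjusted p = 3.44e-07), SLC3A2 2.74-fold (1.45 ± 0.16) and ASNS 2.27-fold (1.18 ± 0.14). CHAC1 rose by 3.44 ± 0.21 from vehicle arrays that both lay at the floor, and so did HSPA6, a strictly inducible HSP70 gene (2.15 ± 0.23, adjusted p = 0.00133). CHAC1 on vehicle arrays lay at 6.5 and 6.17 at 3 h and at 5.61 and 5.35 at 12 h. On 10 nM arrays it lay at 7.37 and 7.52 at 6 h and at 8.28 and 8.13 at 12 h. The larger 6 h than 12 h change of CHAC1, as of DDIT4, thus came with lower vehicle values, which the 2 nM 6 h changes share. Vehicle arrays at 6 h were not tested against other times. The cochaperone gene BAG3 rose 2.09-fold (1.06 ± 0.12) and DNAJB4, an HSP40, 2.32-fold (1.22 ± 0.17). PMAIP1, the BH3-only protein NOXA, rose by 1.26 ± 0.23. TSC22D3 rose by 1.24 ± 0.15 with another probe set at -0.43, and TTC38 by 2.87 ± 0.32 with 2 other probe sets at -0.59 and -0.46. ADAMTS13, a secreted protease, fell to the floor (-1.71 ± 0.18). TNFRSF8 (-1.35 ± 0.24), CKAP4, an ER membrane protein (-1.08 ± 0.19), the transcription factor NFE2L3 (-1.03 ± 0.15), the laminin chain LAMC1 (-0.87 ± 0.15) and the Wnt inhibitor DKK1 (-0.84 ± 0.15) were lower. In all 29 genes passed, 20 higher and 9 lower, 12 of the higher and 4 of the lower also at 12 h. Heat shock genes rose as a group, 4 of 21 over all genes and 11 adjusted over the list alone (median 0.33, camera adjusted p = 4.77e-11, adjusted p = 0.00117 with an estimated correlation). So did ATF4 and CHOP targets, 7 of 32 over all genes and, adjusted over the list alone, 17 higher and 1 lower (median 0.45, adjusted p = 1.07e-17, adjusted p = 0.000185 with an estimated correlation). The translocon list had 0 of 22 members past the test over all genes or over the list alone (limma, 916 genes below an unadjusted p of 0.05), with TRAM1 at 0.39. Its median was 0.13 and its camera adjusted p 0.00923, which became 0.218 with an estimated correlation and 0.0809 without 10 nM 6 h replicate 1. HSPA5 lay at -0.72 ± 0.15 (adjusted p = 0.0676). The count was 11 to 19 without any 1 array other than the 2 nM 6 h and 10 nM 12 h arrays and was 3, all higher, on the deposited intensities. DDIT4, CHAC1, TTC38, HSPA6, SLC3A2, TSC22D3, ASNS, BAG3 and ADAMTS13 passed whichever array was left out. The ACTB 3' to 5' ratio was 1.47 and 1.28 on the 10 nM 6 h arrays against 1.2 and 1.04 on vehicle arrays, and the GAPDH ratio 1.41 and 1.36 against 1.32 and 1.32.

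At 3 h, DDIT4 was 4.07-fold higher at 10 nM (2.02 ± 0.18, n = 2 per group, adjusted p = 0.00103) and passed whichever array was left out. DPH5, an enzyme of diphthamide synthesis, was the other gene past the test (-3.03 ± 0.39, to the floor, adjusted p = 0.0192), but its second probe set lay at 0.01. These 2 genes became 38 without 10 nM 3 h replicate 2 and 1 without vehicle 6 h replicate 2 or either 2 nM 6 h array. With 1 scaling factor per array they were 3, 2 of them higher. No member of the heat shock list passed over all genes (limma, 445 genes below an unadjusted p of 0.05). Of 21 members 5 rose adjusted over the list alone, among them DNAJB1 at 0.91 ± 0.14 and BAG3 at 0.76 ± 0.12 (median 0.09, camera adjusted p = 3.29e-05, adjusted p = 0.0151 with an estimated correlation). ERK output genes were lower as a group, with MYC at -0.41 ± 0.1, IER3 at -0.35 and the ERK phosphatase DUSP4 at -0.71 ± 0.31. Of 19, 0 passed over all genes and 1 fell adjusted over the list alone (median -0.18, camera adjusted p = 0.000488, adjusted p = 0.0346 with an estimated correlation). On the deposited intensities the median of this list was 0.03 (camera adjusted p = 0.0269). ATF4 and CHOP targets had a median of 0.07, 1 of 32 higher over all genes and 3 adjusted over the list alone (camera adjusted p = 0.00377, adjusted p = 0.0514 with an estimated correlation). The ACTB ratio was 1.3 and 1.26 on the 10 nM 3 h arrays against 1.01 and 1.15 on vehicle arrays, while the GAPDH ratio was 1.33 and 1.3 against 1.24 and 1.37. HSPA5 (-0.27 ± 0.15) and STAT3 (0.04 ± 0.16) did not pass.

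At 2 nM and 12 h, SLC3A2 rose 5.24-fold (2.39 ± 0.16, n = 2 per group, adjusted p = 2.65e-05), CHAC1 3.73-fold (1.9 ± 0.21), DDIT4 3.37-fold (1.75 ± 0.18) and ASNS 2.75-fold (1.46 ± 0.14). These 4 passed whichever array was left out. PSAT1 (1.38 ± 0.22) and TTC17 (1.45 ± 0.17) also rose. CRELD2, an ER stress-inducible protein, was the 1 gene that fell (-0.95 ± 0.12, adjusted p = 0.00677) of the 9 that passed. The count was 5 without vehicle 12 h replicate 1, and 1, a higher gene, on the deposited intensities. The ATF4 and CHOP list had a median of 0.53, with 5 of 32 higher over all genes and 22 adjusted over the list alone (camera adjusted p = 1.96e-34, adjusted p = 1.68e-05 with an estimated correlation). Heat shock genes (median 0.15, adjusted p = 0.00173) also kept their call with an estimated correlation (adjusted p = 0.0479). ER chaperones had a median of -0.13 with 1 higher and 1 lower of 24 over all genes, and 2 higher and 5 lower adjusted over the list alone. Their camera adjusted p was 0.0189, with adjusted p = 0.108 with an estimated correlation and 0.146 without vehicle 12 h replicate 2. Smaller shifts passed for NRF2 targets (median 0.11, adjusted p = 0.000459), cholesterol synthesis (-0.16, 0.005), ribosomal proteins (-0.08, 0.0067), the translocon (0.07, 0.0126) and G1/S (-0.07, 0.0358). All 5 were lost with an estimated correlation, at adjusted p = 0.0953, 0.0697, 0.569, 0.232 and 0.113. Leaving out 1 array ended the call for cholesterol synthesis (2 nM 12 h replicate 2, adjusted p = 0.068) and for ribosomal proteins (vehicle 12 h replicate 1, 0.0704, or 2 nM 12 h replicate 1, 0.325). The translocon call was lost without the same arrays (0.0545 and 0.149). The G1/S call was lost without any 1 of 5 arrays (vehicle 12 h replicate 2, 0.269, 2 nM 12 h replicate 1 or 2, 0.0601 and 0.158, or 10 nM 12 h replicate 1 or 2, 0.0632 and 0.0633). On the deposited intensities the heat shock, NRF2, translocon and G1/S calls were lost (adjusted p = 0.336, 0.261, 0.546 and 0.092), and with 1 scaling factor per array the translocon call (0.0635). HSPA5 (-0.54 ± 0.15, adjusted p = 0.29), DDIT3 (0.63 ± 0.2, adjusted p = 0.396), FGFR4 (0.58 ± 0.19, adjusted p = 0.451) and IL6ST (0.44 ± 0.13, adjusted p = 0.342) did not pass.

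After 6 h of 2 nM, DDIT4 rose by 3.6 ± 0.18 from close to the floor (n = 2 per group) and SLC3A2 3.21-fold (1.68 ± 0.16). CHAC1 rose by 2.65 ± 0.21 and HSPA6 by 1.68 ± 0.23 from the floor. BAG3 rose too (0.83 ± 0.12), and ADAMTS13 (-1.71 ± 0.18) and the kinase PRP4K (-1.15 ± 0.16, with another probe set at 0.11) fell. In all 11 genes passed, 9 of them higher. Without vehicle 6 h replicate 2 or 2 nM 6 h replicate 2 the count was 7. Among ATF4 and CHOP targets 3 of 32 were higher over all genes, and 12 higher and 1 lower adjusted over the list alone (median 0.36, camera adjusted p = 5.51e-15, adjusted p = 0.000284 with an estimated correlation). Among heat shock genes 2 of 21 were higher over all genes and 9 adjusted over the list alone (median 0.31, camera adjusted p = 5.32e-09, adjusted p = 0.00228 with an estimated correlation). NRF2 targets (median 0.12, adjusted p = 0.00173) and growth factor receptors (median 0.21, adjusted p = 0.0127, with EGFR at 0.73 ± 0.2) shifted upward too, but lost their calls with an estimated correlation (adjusted p = 0.125 and 0.227). The NRF2 call was also lost on the deposited intensities (0.0871). The receptor call was also lost without vehicle 6 h replicate 1 (0.188) or 2 nM 6 h replicate 1 (0.0722). At 3 h of 2 nM, DDIT4 was 2.58-fold higher (1.37 ± 0.18, adjusted p = 0.0315) and TP53I3, a p53 target, lower at the floor (-2.23 ± 0.21, adjusted p = 0.00155), and no other gene passed. That count was 1 to 5 without any 1 array other than those of vehicle 6 h, 2 nM 6 h and 10 nM 12 h. Heat shock genes (median 0.1, adjusted p = 0.000459) passed at 3 h also with an estimated correlation (adjusted p = 0.0346). The calls of ERK output genes (-0.14, 0.0152), ribosomal proteins (0.06, 0.0163) and ATF4 and CHOP targets (0.06, 0.0475) were lost with one, at adjusted p = 0.0953, 0.601 and 0.125. The ERK call was lost without vehicle 3 h replicate 2 (0.262) or 2 nM 3 h replicate 1 (0.122). The ribosomal call was lost without vehicle 3 h replicate 1 (0.0526) or 2 (0.119) or 2 nM 3 h replicate 2 (0.476), and the ATF4 call was lost without any 1 array other than those of 2 nM and 10 nM at 6 h (0.0537 to 0.257). None of the 4 calls at 3 h held on the deposited intensities, with adjusted p = 0.118 for heat shock genes, 0.2, 0.762 and 0.118, and with 1 scaling factor per array the ribosomal call was lost (0.934).

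Between 10 nM and 2 nM the tested differences were few. At 12 h, HABP2, a plasma serine protease (1.22 ± 0.18), MAB21L4 (0.93) and PPIH, a cyclophilin (0.92), were higher at 10 nM. HP1BP3, a chromatin protein (-2.48 ± 0.33), DPH5 (-2.36, with its other probe set at 0.26) and the deacetylase HDAC7 (-1.92) were lower, within 10 genes past the test. Targets of ATF4 and CHOP were higher at 10 nM than at 2 nM as a group (median 0.29, camera adjusted p = 8.98e-07, adjusted p = 0.00615 with an estimated correlation). Of the members 0 passed over all genes (limma, 1000 genes below an unadjusted p of 0.05) and 5 adjusted over the list alone. Both mean 3' to 5' ratios were also higher at 10 nM (GAPDH 1.61 against 1.24, ACTB 1.22 against 1.13), so RNA quality stays open for this difference. Ribosomal proteins had a median difference of 0.1 (adjusted p = 0.00892, adjusted p = 0.451 with an estimated correlation). HSPA5 lay at -0.55 ± 0.15 without passing (adjusted p = 0.185). The count at 12 h ranged from 1 without 2 nM 12 h replicate 1 to 67 without 10 nM 12 h replicate 1, and moved by over 1.5 times also without any 1 of the 3 h arrays or the 2 nM 6 h arrays. It was 3 on the deposited intensities, all lower, with a median of all genes of -0.78. At 6 h 0 genes passed with limma and 563 lay below an unadjusted p of 0.05. The genes with the largest moderated statistics were PAPPA2 (-1.02 ± 0.16, adjusted p = 0.221, with another probe set at 0.38) and LAMC1 (-0.88 ± 0.15, adjusted p = 0.238). Without 10 nM 6 h replicate 2 the 6 h count was 6, without 2 nM 6 h replicate 1 it was 4 and without either 10 nM 3 h array it was 1. NRF2 targets had a median of -0.16 (adjusted p = 0.0265, adjusted p = 0.292 with an estimated correlation). At 3 h, TP53I3 (2.07 ± 0.21) and BTN2A2 (1.97 ± 0.26, with another probe set at -0.39) were higher at 10 nM and DPH5 (-3.08 ± 0.39, with its other probe set at 0.14) and ACTBP9 (-2.27 ± 0.32) lower, 4 genes in all. The count became 40 without 10 nM 3 h replicate 2, 0 without replicate 1 (limma, 301 genes below an unadjusted p of 0.05) and 1 without either 2 nM 6 h array. On the deposited intensities it was 3, 2 of them higher. The doses share their vehicle arrays. Changes at 10 nM and 2 nM correlated across 8002 genes at r = 0.49, 0.63 and 0.39 at 12 h, 6 h and 3 h, where simulated unchanged groups gave 0.5 at each time. The covariances were 0.0588, 0.0808 and 0.0322 against 0.0362, 0.0363 and 0.0362 simulated. Of the 8 genes higher at 2 nM and 12 h all 8 were also higher at 10 nM. The 2 vehicle arrays of a time were not split between the doses, so part of that overlap can come from them.

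The response to 10 nM differed between 12 h and 3 h in 6 genes by the interaction test. SLC3A2 (1.83 ± 0.22, adjusted p = 0.0209), ASNS (1.58 ± 0.2, adjusted p = 0.0218) and TRIB3, a pseudokinase induced by ATF4 (1.07 ± 0.16, adjusted p = 0.0443), had the higher change at 12 h. PCSK7 (-2.59 ± 0.4), NPTXR (-1.68 ± 0.24) and the integrin subunit ITGB1 (-0.96 ± 0.15, with another probe set at 0.16) had the lower one. TRIB3 lay at -0.28 on the deposited intensities. The ATF4 and CHOP list as a group had the higher change at 12 h (median 0.68, 3 of 32 higher over all genes and 20 adjusted over the list alone, camera adjusted p = 5.54e-24, adjusted p = 7.49e-05 with an estimated correlation). For ERK output genes (0.17, adjusted p = 0.0265), NRF2 targets (0.16, 0.0394), ER chaperones (-0.36, 0.0397) and cholesterol synthesis (-0.21, 0.0265) the differences were lost with an estimated correlation, at adjusted p = 0.149, 0.323, 0.184 and 0.149. The count of 6 became 30 without 10 nM 3 h replicate 2, 16 without 10 nM 12 h replicate 1 and 0 without vehicle 3 h replicate 1 or 10 nM 3 h replicate 1 (limma, 837 and 551 genes below an unadjusted p of 0.05). It moved by over 1.5 times without any 1 array except 2 nM 3 h replicate 1, vehicle 12 h replicate 2 and 10 nM 12 h replicate 2. On the deposited intensities 5 genes passed, all lower, around a median of -1.21, and with 1 scaling factor per array 5, with 3 higher. Across 8002 genes the 10 nM changes at 12 h and 6 h, which share no arrays, correlated at r = 0.11. Of the genes past the test 12 were higher at both times against 0.2 for independent lists, and 4 were lower at both against 0.1.

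Vehicle arrays themselves differed between 12 h and 3 h in 35 genes, 21 higher and 14 lower. CYP1A1, an enzyme of xenobiotic metabolism, named after its value was seen, was 4.03-fold lower at 12 h (-2.01 ± 0.13, n = 2 per group, adjusted p = 3.63e-05) and passed whichever array was left out. G2/M genes had a median of -0.22 (camera adjusted p = 0.00182) and ERK output genes of 0.23 (adjusted p = 0.0265), both lost with an estimated correlation (adjusted p = 0.149 for each). The count was 3 without vehicle 3 h replicate 2 or vehicle 12 h replicate 1, 6 without vehicle 3 h replicate 1, and 9 without vehicle 12 h replicate 2. It was 21 to 23 without 2 nM 3 h replicate 2, either 10 nM 3 h array or vehicle 6 h replicate 2.

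**Figure D2:**
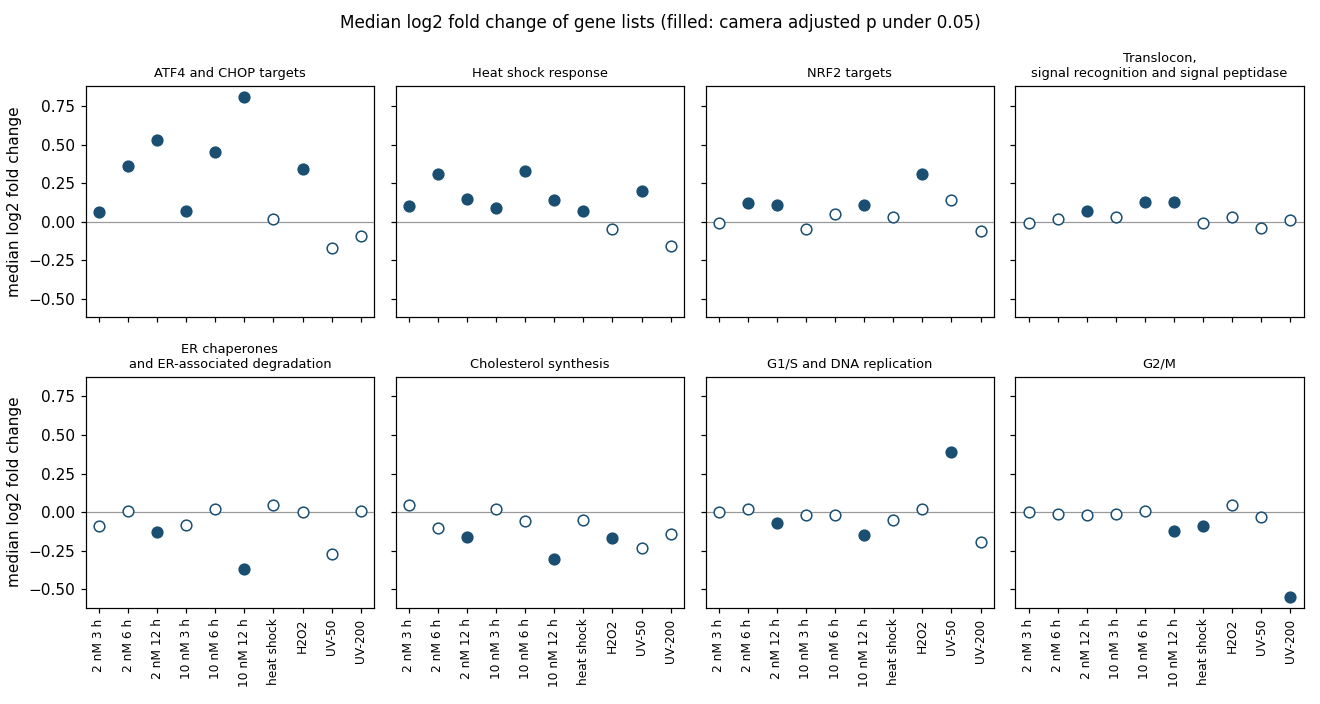
Median log2 fold change of 8 gene lists (vertical axis) in the 10 comparisons with vehicle or untreated arrays (horizontal axis), with filled points where camera's adjusted p with the preset correlation was under 0.05. ATF4 and CHOP targets stand at 0.81 for 10 nM at 12 h and at 0.34 for hydrogen peroxide, and ER chaperones at -0.37 for 10 nM at 12 h.

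Heat shock for 1 h, measured at 12 h, left HSPB1, the small heat shock protein HSP27, 2.49-fold higher (1.31 ± 0.11, n = 2 per group, adjusted p = 0.0225). GUCA2A, the intestinal hormone guanylin, rose by 1.26 ± 0.13 from the floor, and PDE4D, a cyclic AMP phosphodiesterase, fell to close to the floor (-1.22 ± 0.11, with another probe set at 0.11). These 3 genes were all that passed. The count was 0 (limma, 273 to 508 genes below an unadjusted p of 0.05) without any 1 array except the UV-200 array and UV-50 replicate 1 (5 without the latter). It was 2 with 1 scaling factor per array (1 of them higher) and 12 on the deposited intensities (11 of them higher). Heat shock genes shifted upward (median 0.07, 1 of 20 higher over all genes and 2 adjusted over the list alone, with SERPINH1 at 0.55 ± 0.12). Their camera adjusted p was 0.00114, and adjusted p = 0.113 with an estimated correlation. Interferon-stimulated genes (median 0.18, adjusted p = 0.00377) and G2/M genes (-0.09, 0.00389) were lost with an estimated correlation (adjusted p = 0.507 and 0.116). The former was also lost without untreated replicate 2 (0.136) or heat shock replicate 1 (0.134), and the latter on the deposited intensities (0.224).

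After hydrogen peroxide, AKR1C2, an aldo-keto reductase that NRF2 induces, was 2.2-fold higher (1.14 ± 0.1, n = 2 per group, adjusted p = 0.0197). SLC7A5, the amino acid transporter that pairs with SLC3A2, was 2-fold higher (1 ± 0.1, adjusted p = 0.0254). KCNH2, a potassium channel, rose by 1.33 ± 0.1 from the floor with another probe set at 0, and PDE4D fell to close to the floor (-1.26 ± 0.11). The count of 4 was 0 without either untreated array, either hydrogen peroxide array or heat shock replicate 1 (limma, 429 to 954 genes below an unadjusted p of 0.05) and 1 without heat shock replicate 2. It was 17 on the deposited intensities (10 of them higher). Targets of ATF4 and CHOP shifted upward, 1 of 30 over all genes and 14 adjusted over the list alone, with ASNS at 1.29 ± 0.16 and WARS1 at 0.66 ± 0.1 (median 0.34, camera adjusted p = 1.25e-13, adjusted p = 0.0928 with an estimated correlation). NRF2 targets shifted upward too, 1 of 23 over all genes and 9 adjusted over the list alone, with AKR1C3 at 0.85 ± 0.1 and AKR1B10 at 0.68 (median 0.31, adjusted p = 2.57e-10, adjusted p = 0.0346 with an estimated correlation). Cholesterol synthesis (-0.17, adjusted p = 0.000459) and interferon-stimulated genes (0.19, adjusted p = 0.0127) were lost with an estimated correlation (adjusted p = 0.147 and 0.569). The latter was also lost without untreated replicate 2 (0.241) or hydrogen peroxide replicate 1 (0.226) and without the filter on dim genes (0.134).

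Far more genes passed after UV-50. PMAIP1 rose 3.93-fold (1.98 ± 0.29, n = 2 per group, adjusted p = 0.00465), ADM, the peptide hormone adrenomedullin, 3.2-fold (1.68 ± 0.13) and HEXIM1, an inhibitor of transcription elongation, 2.99-fold (1.58 ± 0.22). ULBP2, a ligand of the natural killer receptor NKG2D, rose by 1.89 ± 0.14 from the floor. FAF1, a Fas-associated factor (-2.77 ± 0.14, adjusted p = 0.000241), the receptor ROR1 (-2.44 ± 0.21) and the formin DIAPH2 (-2.31 ± 0.1) fell the most. The phosphatase PTPRK fell 4.93-fold (-2.3 ± 0.11). Next were FRY (-2.21 ± 0.16) and SNTB1 (-2.21 ± 0.13, with other probe sets at -2.86 and 0.02). All but PTPRK ended close to the floor, where folds depend on the pseudocount. Genes of G1/S and DNA replication rose, 17 of 33 with 1 lower (18 and 2 adjusted over the list alone). Among them were CCNE2, cyclin E2 (1.27 ± 0.15), the nuclease FEN1 (0.88 ± 0.09) and SLBP, the histone mRNA binding protein (0.78 ± 0.1). The list had a median of 0.39 (camera adjusted p = 0.000114, adjusted p = 0.0791 with an estimated correlation). Interferon-stimulated genes had 6 of 21 higher (7 adjusted over the list alone), such as TAP1 (1.26 ± 0.13) and IRF1 (0.89 ± 0.1). NF-kappaB and chemokine genes had 4 of 15 (6 alone), such as NFKBIA (0.79 ± 0.09) and CXCL8 (0.7 ± 0.11), and heat shock genes 5 of 20 (6 alone), such as SERPINH1 (0.9 ± 0.12). Their medians of 0.52, 0.28 and 0.2 had camera adjusted p of 0.000799, 0.01 and 0.0307, and 0.459, 0.187 and 0.237 with an estimated correlation. The heat shock call was lost without UV-50 replicate 2 (0.0858) or untreated replicate 1 (0.0797) and on the deposited intensities (0.0717). Among p53 targets 5 rose and 3 fell of 19 (median 0.25, adjusted p = 0.343). Among ATF4 and CHOP targets 2 rose and 7 fell of 30 (median -0.17, adjusted p = 0.167), with SLC7A11 at -0.95 ± 0.12. In all 1712 of 7482 genes passed, 805 higher and 907 lower. The count was 644 without UV-50 replicate 1, 1055 without replicate 2, 798 without untreated replicate 1 and 722 without replicate 2. It was 291 on the deposited intensities, with 76 higher and 215 lower.

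The single UV-200 array differed from untreated arrays in 3225 genes, 1465 higher and 1760 lower. It was assumed to vary like arrays of the other groups, so its p-values rest on their spread and do not measure its own variation, and its values have no replicate. PMAIP1 was 18.1-fold higher (4.18 ± 0.36, adjusted p = 0.000204), the EGF receptor ligand HBEGF 11.9-fold (3.58 ± 0.31), the stress transcription factor ATF3 10.9-fold (3.44 ± 0.23) and FOS 10.3-fold (3.37 ± 0.31). CCN2 was 9.94-fold (3.31 ± 0.23) and CITED2 8.16-fold higher (3.03 ± 0.13). BMP4, a morphogen (-4.74 ± 0.17, adjusted p = 2.1e-05), the death domain adaptor FADD (-3.64 ± 0.15) and the corepressor NRIP1 (-3.54 ± 0.12) were lower and close to the floor. TCF7L2, a transcription factor of the Wnt pathway, was 10.7-fold lower (-3.42 ± 0.12). The kinase CDK7 (-3.68 ± 0.13) lay at the floor. Immediate early genes were higher as a group, 16 higher and 3 lower of 24 (17 and 5 adjusted over the list alone), KLF4 at 2.72 ± 0.17 and MYC at -1.55 ± 0.14 among them. Their median was 1.18 (camera adjusted p = 0.00249, adjusted p = 0.514 with an estimated correlation). G2/M genes were lower, 25 of 41 with 1 higher (25 and 3 adjusted over the list alone), such as AURKA (-2.5 ± 0.18) and CCNA2 (-2.34 ± 0.23). Their median was -0.55 (adjusted p = 0.000156, adjusted p = 0.0791 with an estimated correlation). Growth factor receptors were lower in 10 of 17 with 1 higher (12 and 1 adjusted over the list alone), with TGFBR2 at -2.58 ± 0.18 and MET at -1.16 ± 0.12. The list median was -0.85 (adjusted p = 0.00603, adjusted p = 0.372 with an estimated correlation). Mesenchymal markers (4 of 8 higher, median 0.72, adjusted p = 0.0304) included TAGLN (1.32 ± 0.16) and COL1A1 (1.34). Interferon-stimulated genes (8 higher and 2 lower of 21, median 0.58, adjusted p = 0.0358) included IRF7 (1.68 ± 0.13). Both were lost with an estimated correlation (adjusted p = 0.342 and 0.601) and with 1 scaling factor per array (0.071 and 0.0912). The mesenchymal call was also lost without the filter on dim genes (0.32), and the interferon call without UV-50 replicate 2 (0.0523), untreated replicate 2 (0.0912) or either hydrogen peroxide array (0.0535 and 0.0553).

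**Figure D3:**
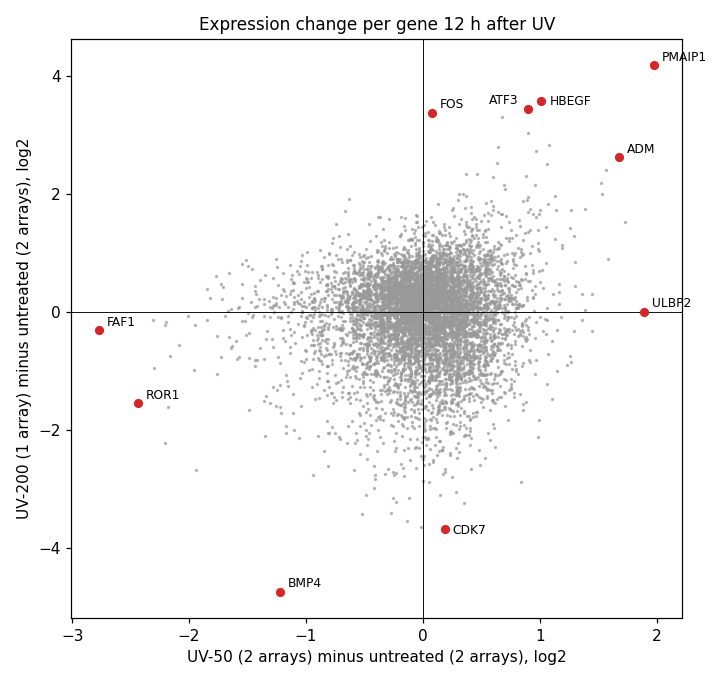
Log2 fold change of each of 7482 genes after UV-50 (horizontal axis, 2 arrays) and UV-200 (vertical axis, 1 array), each against the same 2 untreated arrays, with the named genes in red. PMAIP1 stands at 1.98 and 4.18, FAF1 at -2.77 on the horizontal axis and BMP4 at -4.74 on the vertical axis.

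The balance of directions at UV-200 depended on the scaling. With 1 scaling factor per array 3502 genes passed, 1249 higher and 2253 lower, around a median of all genes of -0.09. On the deposited intensities 2712 passed, 56 higher and 2656 lower, around a median of -0.62. Ribosomal protein genes had a median of 0.06 (adjusted p = 0.343), 0.62 with 1 scaling factor (adjusted p = 1.96e-16) and -0.07 on the deposited intensities (adjusted p = 1.43e-06, above the median of all genes). FGFR1 (1.08 ± 0.16) was higher and FGFR2 (-1.75 ± 0.2) and FGFR3 (-1.41 ± 0.2) lower at UV-200. In the FGF list 7 members were higher and 5 lower of 19 (median 0.4, adjusted p = 0.605). STAT3 was at 0.51 ± 0.12 (adjusted p = 0.014), but at -0.32 on the deposited intensities. The GAPDH and ACTB 3' to 5' ratios of the UV-200 array were 1.13 and 1.13, against 0.97 and 0.97 and against 0.92 and 0.96 on the untreated arrays. Between UV-200 and UV-50, 3863 genes differed, 1863 higher and 2000 lower at UV-200. The highest by the naming rule were FOS (3.28 ± 0.31), CCN2 (2.64) and HBEGF (2.57), and the lowest CDK7 (-3.87 ± 0.13), KEAP1 (-3.72 ± 0.15) and FADD (-3.62). Of the 2980 that differed on the deposited intensities 91 were higher, around a median of -0.61. As groups, G1/S genes (median -0.5, 26 of 33 below 0 and 7 above) and G2/M genes (-0.46, 31 of 41 below and 10 above) were lower at UV-200 than at UV-50. So were heat shock genes (-0.38, 17 of 20 below and 3 above). Immediate early genes were higher (median 0.59, 17 of 24 above 0 and 7 below). Camera called these 4 shifts with the preset correlation and none of them with an estimated one. The responses to the 2 UV doses share the untreated arrays and correlated at r = 0.09 across 7482 genes, below the 0.41 of simulated unchanged groups. The covariance was 0.0303 against 0.0137 simulated. Called higher at both doses were 221 genes and lower at both 257, while 212 were higher at UV-50 and lower at UV-200 and 156 the reverse. Shared untreated arrays add to the overlaps in the same direction, and the directions at UV-200 depend on the scaling.

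The apratoxin response was set against the stress responses, which have separate controls. Across 7248 genes the 10 nM changes at 12 h correlated with those after heat shock at r = -0.04, hydrogen peroxide at 0.03, UV-50 at -0.03 and UV-200 at 0.06. Genes are not independent replicates. Of 76 genes higher at 10 nM that were tested in both sets, 14 were also higher after UV-50 (8.2 by independent lists) and 17 after UV-200 (15), while 12 were lower after UV-50 (9.2) and 23 after UV-200 (18.1). Of 63 lower genes 8 were lower after UV-50 (7.7) and 18 after UV-200 (15), while 6 were higher after UV-50 (6.8) and 10 after UV-200 (12.4). Over the 141 genes past the test in either comparison, the correlation with hydrogen peroxide was 0.33. Of these genes 139 passed at 10 nM and 3 after hydrogen peroxide. HSPB1 was higher after heat shock and at 10 nM and 12 h, the 1 gene shared by those lists, and SLC7A5 was the 1 shared with hydrogen peroxide. Heat shock and hydrogen peroxide, which share the untreated arrays, correlated at r = 0.55 across 7482 genes (0.5 for simulated unchanged groups, covariance 0.0256 against 0.0136).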

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

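Tests of RNA quality, of the dim array and of normalization in what follows were chosen only after the results were seen, and so were the normalization tests of UV-200. Between time points, 6 genes differed in their 10 nM response by the interaction test: 12 h minus 3 h, SLC3A2 by 1.83, ASNS by 1.58, TRIB3 by 1.07, PCSK7 by -2.59, NPTXR by -1.68 and ITGB1 by -0.96 log2. That count was 0 without vehicle 3 h replicate 1 or 10 nM 3 h replicate 1 (limma, 837 and 551 genes below an unadjusted p of 0.05), 30 without 10 nM 3 h replicate 2 and 16 without 10 nM 12 h replicate 1. The median difference of the ATF4 and CHOP targets was 0.68. In the control probe sets, which the comparisons do not use, the 3' to 5' ratios of ACTB and GAPDH did not move together. The mean ACTB ratio was 1.28 at 10 nM and 3 h with both arrays above their vehicle arrays (1.01 and 1.15), where the mean GAPDH ratio was 1.31 in both groups. The mean GAPDH ratio was 1.61 at 10 nM and 12 h (vehicle 1.36 on both), where the mean ACTB ratio was 1.22 and below the vehicle's 1.35. On the UV-200 array the GAPDH ratio was 1.13 and the ACTB ratio 1.13, above the untreated arrays (0.97 and 0.97, 0.92 and 0.96).

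ATF4 and CHOP targets were higher at 10 nM and 12 h (median 0.81) while ER chaperones were lower (median -0.37). The call of the chaperones was lost with an estimated correlation (camera, adjusted p = 0.0543). For the ATF4 targets, worse RNA by the GAPDH ratio was argued against as the cause by the 2 nM 12 h arrays. Their GAPDH ratios of 1.28 and 1.2 lay below the vehicle's and the list's median was still 0.53. The ACTB ratios lay below the vehicle's (1.3 and 1.41) at 10 nM (1.25 and 1.19) and at 2 nM (1.11 and 1.15). Both doses share these vehicle arrays, so the 2 nM arrays cannot decide on a difference in RNA quality of that kind. The dim array was argued against by a median of 0.78 without it. In the deposited values the list median was -0.28, but it lay 0.69 above that of all genes (0.78 with 1 scaling factor). This argues against normalization as the cause of the list's rise relative to other genes. Setting the list against all genes itself centres the arrays, so it cannot decide whether the list rose in absolute level. For the chaperones, the median without the dim array was -0.28 (adjusted p = 0.00227), without the other 10 nM array -0.24 (adjusted p = 0.0306), and relative to all genes -0.4 with 1 scaling factor per array (adjusted p = 0.00133), so neither accounts for the whole shift. RNA quality stays open for the chaperones, since the 2 ratios went apart at 10 nM, and at 2 nM their median was -0.13, between the bounds set for either outcome, and lost its call with an estimated correlation (adjusted p = 0.108). A response to apratoxin A in which both groups move apart is a hypothesis that may hold, found and tested on the same arrays.

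Genes called lower at 10 nM and 12 h often lay near the floor: 32.4% of them (22 of 68) had a 10 nM mean under a log2 value of 5, against 9.76% of the genes called higher (8 of 82) at their vehicle end. The share lay between the 25% and 50% set beforehand, so a loss of dim signal may contribute to part of the lower calls. Replicate 2 of the 10 nM arrays was the dimmest (median 13.33, replicate 1 22.58, vehicle replicate 1 23.43). For those 22 genes, whose lower end lies near the floor, such a loss cannot be told apart from a response to the drug. All 68 kept their direction and at least 50% of their size without replicate 2, and likewise without replicate 1. These genes were picked for passing with both arrays, so this does not decide the question. Disagreement between probe sets is argued against as the general cause, since 83.9% of the 31 other probe sets of 22 lower genes pointed lower too, against 78.9% of 38 for the higher genes. DPH5, LAIR1, BRF1 and KIF1C are exceptions, with other probe sets at or above 0.

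At UV-200, 51.1% of the genes called higher (749 of 1465) lay at or below 0 in the deposited values, and all 1760 lower calls stayed lower there. Both shares largely restate the median of all genes of -0.62 in those values, since a shift by that median alone would put 33.7% of the higher calls at or below 0, and 1 scaling factor, which centres the array again, leaves 1463 of them above 0. They therefore decide nothing, and normalization stays open for the higher calls as a whole. For the immediate early genes, normalization as the whole cause is argued against by the deposited values, where the median of the 24 members was 0.37 (adjusted p = 5.18e-09) and the median of all genes -0.62. The call was lost with an estimated correlation (adjusted p = 0.514). Whether the array held less RNA signal or was only dimmer cannot be told apart: its 9 spike-in probe sets lay -0.58 from the untreated arrays beside -0.62 for the median gene, but on other stress arrays spike-ins lay between -0.73 and 0.22 with gene medians between -0.21 and 0.34. UV dose as a biological cause stays open, with 1 array and no replicate.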

How the results depend on the processing

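The alternatives of 1 scaling factor per array, a floor of 16 and a pseudocount of 64 were chosen only after the data were seen, and the others before. The planned log2(value + 16) is the setting reported. Signal over background limits dim genes, since values below 0 share the floor, and 2 arrays per group limit every count. The values that follow are numbers of genes past an adjusted p of 0.05 (limma) unless said otherwise. Where no reason is given the cause was not tested. Counts of 0 had 398 to 1072 genes below an unadjusted p of 0.05 within only the groups compared, 288 to 527 without the arrays of conflicting labels, 581 to 850 with the replicate block, 844 to 1152 without the filter, 42 on the deposited values and 273 to 954 with 1 array left out. Values of named genes under alternatives with a test were sorted by whether the gene passed as reported. Kept were 20922 values, either past the threshold in the same direction or, for genes not past it, within 1 SE. Of genes past it as reported, 1264 values were no longer past it and 16 reversed. Of genes not past it, 76 values were newly past it and 1016 moved by over 1 SE. For lists, 2138 values kept their call and direction or stayed uncalled, whatever their direction. Of the rest 89 were no longer called, 30 were newly called and 11 called lists reversed, by camera's direction or the sign of the median. The UV-200 comparisons have no value without their single array.

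On the deposited values without normalization the counts were 38 for 10 nM at 12 h, 3 at 6 h, 1 for 2 nM at 12 h, 4 at 6 h and 0 at 3 h. They were 3 between 10 nM and 2 nM at 12 h, 1 at 6 h, 3 between vehicle arrays at 12 h and 3 h, 12 for heat shock, 17 for hydrogen peroxide and 291 for UV-50. The median of all genes lay at -0.97, 0.22 and 0.25 for 10 nM at 12 h, 6 h and 3 h, and at -0.19 and 0.14 for 2 nM at 12 h and 3 h. It lay at -0.78, 0.25 and 0.11 between the doses at 12 h, 6 h and 3 h, -1.21 for the interaction, 0.35 for vehicle, 0.19 for heat shock, -0.62 for UV-200 and -0.61 between the UV doses. That shift of all genes turned the direction of genes called higher: at 10 nM and 12 h ACVR1B (-0.34), TRAM1 (-0.56), SRPRB (-0.55), SEC62 (-0.36), HSPH1 (-0.4), HSPB1 (-0.28), GDF15 (-0.34), SLC7A11 (-0.02) and ATF3 (-0.06), in the interaction TRIB3 (-0.28), and at UV-200 STAT3 (-0.32), AKR1C2 (-0.03), CEACAM5 (-0.21), ACTA2 (-0.2) and HBB (-0.18). List medians turned sign with it, although camera tests a list against all other genes. At 10 nM and 12 h they lay at -0.95 for the translocon, -0.28 for ATF4 and CHOP targets (adjusted p = 1.9e-21, still called upward), -0.92 for heat shock genes and -0.95 for NRF2 targets. At 2 nM and 12 h they lay at -0.16, -0.09 and -0.12 for the translocon, heat shock genes and NRF2 targets, at 10 nM and 3 h at 0.03 for ERK output genes (adjusted p = 0.0269), after heat shock at 0.12 for G2/M, and at UV-200 at -0.15 for interferon-stimulated genes and -0.02 for mesenchymal markers (adjusted p = 0.0269 and 0.0319). With a floor of 16, TAP1 at UV-200 lay at 0.

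Without the filter on dim genes the counts were 59 for 10 nM at 6 h, 5 at 3 h, 16 for 2 nM at 12 h and 37 at 6 h. They were 35, 2 and 8 between 10 nM and 2 nM at 12 h, 6 h and 3 h, 12 for the interaction, 55 for vehicle, 0 for heat shock and 0 for hydrogen peroxide. With all probe sets of 1 gene symbol they were 17 for 10 nM at 6 h, 1 for 2 nM at 3 h, 6 between the doses at 12 h and 2 for the interaction. Fits of only the groups compared have few residual degrees of freedom and gave 0 for 10 nM at 12 h, 2 at 6 h and 0 at 3 h, and 0, 0 and 0 for 2 nM. They also gave 0 between the doses at 12 h and at 3 h, and 0 for the interaction, vehicle, heat shock and hydrogen peroxide. Without the 2 arrays of conflicting labels, which leaves 2 groups with 1 array, the counts were 75 for 10 nM at 12 h, 12 at 6 h and 0 at 3 h, and 5 and 1 for 2 nM at 6 h and 3 h. They were then 2 between the doses at 3 h, 0 for the interaction and 1 for vehicle. List calls lost there were those of G1/S (adjusted p = 0.162) and cholesterol synthesis (0.0781) at 2 nM and 12 h, and of ERK output genes (0.289), ATF4 and CHOP targets (0.0781) and ribosomal proteins (0.13) at 2 nM and 3 h.

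With the floor of 16 the counts were 8 for 10 nM at 3 h, 18 for 2 nM at 6 h, 2 between the doses at 3 h and 1 for heat shock. With the pseudocount of 64 they were 4 for 10 nM at 3 h, 21, 19 and 1 for 2 nM at 12 h, 6 h and 3 h, 18 between the doses at 12 h, 61 for vehicle and 1 for heat shock. With 1 scaling factor per array every count stayed within 1.5 times. Lists newly called there included ribosomal proteins, upward for 10 nM at 6 h (median 0.11, camera adjusted p = 0.000232) and 3 h (0.07, 0.0115). The same list was newly called with negative medians for 2 nM at 6 h (-0.17, 0.000271) and heat shock (-0.09, 3.36e-05). With each array left out in turn, an array left alone in its group was assumed to vary like the other groups. Counts then ranged from 37 to 163, 11 to 28 and 1 to 38 for 10 nM at 12 h, 6 h and 3 h, and from 5 to 9, 7 to 15 and 1 to 5 for 2 nM. Between the doses they ranged from 1 to 67, 0 to 6 and 0 to 40, for the interaction from 0 to 30 and for vehicle from 3 to 43. In the stress set they ranged from 0 to 5 for heat shock, 0 to 4 for hydrogen peroxide, 644 to 1805 for UV-50, 2399 to 3360 for UV-200 and 3141 to 4000 between the UV doses. List calls, 46 as reported, were 11 with an estimated correlation and 41 to 47 with 1 array left out.

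Replicate numbers of the stress set were to count as pairs only if every correlation between replicate differences exceeded 0.1, which was not met. Differences between replicates 1 and 2 of the groups with 2 arrays correlated at r = 0.31 (hydrogen peroxide and heat shock), 0.08, 0.06, 0.04, 0.01 and 0.11. All were positive, so a difference shared by arrays of the same number is not excluded. With the number as a block 0 genes passed for heat shock, 0 for hydrogen peroxide, 1849 for UV-50, 3344 for UV-200 and 3945 between the UV doses, with 47 list calls.

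The correlation of the 10 nM response at 12 h with heat shock was -0.08 on the deposited values, 0.02 over genes past the threshold in either comparison and -0.05 to -0.01 with 1 array left out. With hydrogen peroxide it was 0.01 without the filter, 0.33 over genes past the threshold in either and 0.01 to 0.06 with 1 array left out. With UV-50 it was -0.02 on the deposited values and without the filter, and -0.04 to -0.02 with 1 array left out. With UV-200 it was 0.14 on the deposited values, 0.07 over genes past the threshold in either and 0.03 to 0.07 with 1 array left out.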

Other observations

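The list tests of tRNA synthetases, histones, proteasome, coat proteins and glycolysis and the comparison of arrays with conflicting labels were chosen only after the results were seen, and the other tests here before their own results. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were higher at 10 nM and 12 h, 4 of 17 over all genes and 7 adjusted over the list alone: CARS1 by 0.86 ± 0.12, SARS1 by 0.83 ± 0.12, WARS1 by 0.76 ± 0.1 and GARS1 by 0.72 ± 0.12 (median 0.32, camera adjusted p = 0.000278, n = 2 per group). The list was also called upward at 2 nM and 12 h (median 0.27, adjusted p = 1.53e-06) and after hydrogen peroxide (median 0.26, adjusted p = 0.00039). After UV-50, 5 of 17 were lower and 0 higher (limma; median -0.21, camera adjusted p = 0.0542, and 0.428 with an estimated correlation). By fry, which does not set a list against the other genes, the adjusted p after UV-50 was 0.00556. Fry gave 0.00556 also for the upward shifts at 10 nM and 12 h and after hydrogen peroxide, and 0.0122 at 2 nM and 12 h. The upward calls were lost with an estimated correlation (adjusted p = 0.407 at 10 nM, 0.259 at 2 nM and 0.259 after hydrogen peroxide). They were also lost without the synthetases that the ATF4 and CHOP list holds, at 2 nM (median 0.11, adjusted p = 0.438), after hydrogen peroxide (median 0.04, adjusted p = 0.759) and at 10 nM, where 10 genes remained with none past the test (median 0.03, adjusted p = 0.786; limma, 1248 genes of all below an unadjusted p of 0.05). Proteasome subunits, coat proteins of ER to Golgi transport and glycolysis genes gave no call in any of the 10 comparisons with camera and the preset correlation. By fry the coat proteins passed at 10 nM and 12 h (adjusted p = 0.0441), and members of all 3 lists passed limma after UV. Of 27 proteasome genes 3 were higher and 1 lower after UV-50, and 1 and 7 on the UV-200 array. The numbers were 2 and 4, and 4 and 5, of 30 coat proteins, and 1 and 3, and 5 and 2, of 19 glycolysis genes.

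Core histone genes, whose polyadenylated transcripts these arrays detect, were higher after UV. After UV-50, 5 of 9 measured rose, with H2BC5 at 1.26 ± 0.2, H2BC6 at 0.97 ± 0.18, H2BC21 at 0.96 ± 0.16 and H2BC12 at 0.66 ± 0.1 (median 0.66, camera adjusted p = 0.00855). On the UV-200 array 5 were higher, with H2BC21 at 2.15 ± 0.2 and H2BC6 at 1.61 ± 0.22 (median 0.73, adjusted p = 0.0084). Both calls were lost with an estimated correlation (adjusted p = 0.542 each). These genes are near-identical in sequence, so their probe sets can read each other's transcripts and the 5 are not independent.

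Hydrogen peroxide and 10 nM apratoxin A at 12 h showed little likeness over all genes (r = 0.03) but r = 0.33 over the 141 genes past the test in either. This set is nearly the apratoxin list alone, since 139 genes passed for apratoxin A and 3 for hydrogen peroxide. Without the 18 ATF4 and CHOP list members among the 141 genes r was 0.18 over 123 genes. That fall was smaller than the one set beforehand as evidence that the list carries the likeness, so this stays undecided. Over the 30 list members measured in both sets the changes ordered alike (Spearman 0.64, Pearson 0.55, one-sided permutation test, p = 9e-05 over 100000 resamples), and 27 were higher in both. Members are not independent of each other, and the 2 sets share no arrays. Hydrogen peroxide and apratoxin A may induce this list in a similar order, as a hypothesis.

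Whether genes lower after UV-50 recovered at the higher dose stays open. The 907 genes lower at UV-50 (median -0.64) had a median of 0 on the UV-200 array, -0.03 from random genes of the same mean expression and within the random lists (-0.05 to 0.09 in 1000 draws). Normalization centres this array, whose median gene lay at -0.62 in the deposited values. At UV-200, 257 of them were called lower and 156 higher.

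The 2 arrays with conflicting labels were set beside both groups in 10 genes. The array titled 2 nM 12 h replicate 2 lay closer to the other 2 nM array than to the 10 nM mean in 9 of them, as for DDIT4 at 7.82 (other 2 nM array 7.69, 10 nM arrays 8.63 and 8.73), and closer to 10 nM for HMGCS1 (6.84; 7.36, 7.02 and 6.74). The array titled vehicle 3 h replicate 2 lay closer to the other vehicle array than to the 2 nM mean in 5 of them, as for DDIT4 at 5.26 (other vehicle array 5.63, 2 nM arrays 6.86 and 6.77) and SLC3A2 at 8.69 (9.07, 9.64 and 9.51), and closer to 2 nM in the other 5. Among those 5 was CHAC1 (6.17; 6.5, 6.42 and 6.26), where the 2 nM arrays lay below the other vehicle array. Spike-in probe sets in the deposited values of the 10 nM 12 h arrays lay -1.52 and -1.93 from the vehicle mean and the median gene -0.71 and -1.22, while the vehicle 12 h arrays differed from their mean by 0.78 and -0.78 for spike-ins and 0.58 and -0.58 for genes.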
